A study of Homo sapiens with 12 samples.

How the data were processed

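Whole skin RNA was sequenced from 12 libraries, 4 of healthy controls (HC), 4 of chronic pruritus of unknown origin (CPUO) and 4 of atopic dermatitis (AD). Per the labels' protocols, tissue was kept in RNAlater, RNA was treated with DNase, ribosomal RNA was removed by hybridization, and complementary DNA was made with random hexamers. The labels name the molecule polyA RNA, while their protocol describes removal of ribosomal RNA, and which of these set the RNA measured is not given in the sources used here. Batch, body site and tissue source of each sample are not given in the sources used here, so none was a term of a model.

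The deposited files hold, for each library, estimated counts of reads per transcript and TPM, per the file headers made with Sailfish 0.6.3 at a k-mer length of 20 on an index of Ensembl release 76 transcripts. The deposited TPM values were not used in the main tests, and served only to weight transcript lengths for the alternative with a transcript length offset. The authors also deposited 1 table of gene CPM, and the submitters' processing notes name bcl2fastq, STAR 2.0.4b and Subread featureCounts 1.4.5. The deposited CPM table also gives the GC content of each gene in percent, which was not used in the tests. In that deposited CPM matrix, 100% of values were whole multiples of 1 read of their library within a tolerance of 0.01, so whole reads were recovered from it for a comparison. Whether reads were counted by strand is not stated, so overlapping and antisense genes cannot be told apart there.

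Transcripts were joined to genes by identifier with GENCODE release 29, which matched 158465 of 170786 transcripts, or 92.8%. Reads of unmatched transcripts were 2.13% to 2.79% of each library. Estimated reads per library ranged from 10551751 to 17643018, and gene sums from 10301258 to 17251740. Between 22811 and 25779 genes were detected per library. Y-linked genes, XIST and TSIX, 418 genes in all, were left out, which left 34213. Gene sums and the deposited CPM table were compared over 14536 genes, where r of log2 values across genes, which are not independent replicates, was 0.909 to 0.937 per library. Coordinates are those of GENCODE release 29 on GRCh38. p-values measure only the spread between libraries, and bounds for genes without reads in a group, taken at a floor of 3 counts over the group, cover counting error only.

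Gene sums were rounded to whole numbers and tested with edgeR 4.0.16 under R 4.3.3, with TMM normalization, the filterByExpr filter by group, which left 19071 genes, and a quasi-likelihood fit of all 12 libraries with 1 mean per group. The 3 contrasts were CPUO against HC, AD against HC and AD against CPUO, two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists of pathways and cell type markers were fixed before the data were examined, as were the tests and the rule for naming genes; 889 of their 905 genes were matched, and 43 of 45 lists had the 5 tested members required. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 129 tests, with an estimated correlation and with fry, directional and mixed, beside it. The labels do not say that libraries with the same number belong together. Deviations from the group means correlated over 0.1 in 4 of 4 such pairs of HC and AD, a hint from the data, so the count with a replicate block is given beside that comparison. For each list the members that passed were counted over all genes and adjusted over the list alone. Principal components were taken from log2 CPM, with a prior count of 2, of the 500 most variable tested genes. A list's level in a library is the mean log2 CPM of its members.

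Genes were named by rule. Among genes that passed, averaged at least 1 CPM over the 12 libraries, and had group ranges without overlap, the 10 with the largest and the 10 with the lowest log2 fold change were taken. Where fewer than 10 passed, genes with the smallest p were added up to 10 and given as values. Up to 4 members with the smallest p of each list described were added, and a preset set of itch, barrier and inflammation genes. Genes without a symbol, sex-linked genes and segments of antigen receptors were never named.

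The pipeline was tested on simulated counts with 200 changed genes for each comparison. For CPUO against HC, over 19011 genes, 20 of 100 genes changed 2-fold and 76 of 100 changed 4-fold were recovered, with 6 false calls. For AD against HC, over 19014 genes, it recovered 19 of 100 at 2-fold and 74 of 100 at 4-fold, with 2 false calls. For AD against CPUO, over 19011 genes, it recovered 31 of 100 at 2-fold and 83 of 100 at 4-fold, with 3 false calls. In these simulations, with 4 libraries per group, a 2-fold difference was therefore missed more often than found. The share recovered after Benjamini-Hochberg adjustment depends on how many genes change. It cannot be carried over as such to the real comparisons, where 784, 1186 and 4 genes passed.

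Alternatives covered other normalizations and filters, a transcript length offset, a term for the replicate number, fits of 2 groups alone, limma-voom without and with sample weights, limma-trend on the deposited CPM table with pseudocounts of 0.1, 0.5 and 1, DESeq2 1.42.0, and leaving out each library in turn. Chosen after seeing the data were edgeR on the recovered reads, fits without HC 2 and HC 4, and fits with the basal keratinocyte or fibroblast level as a covariate. The similarity of the 2 disease effects was set against 20 simulations of unchanged groups and against 6 assignments of different controls for each disease. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.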

Results

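RNA from 12 human skin samples was sequenced, 4 from healthy controls (HC), 4 from people with chronic pruritus of unknown origin (CPUO) and 4 from people with atopic dermatitis (AD). CPUO is a lasting itch for which no cause is found, and AD is an inflammatory and itching skin disease. The samples were punch biopsies or surgical tissue, and which of these each sample was is not given in the sources used here. Body site is not given there either. Differences between groups in tissue source or body site therefore cannot be told apart from disease. The labels do not say whether each library came from a separate person, so p-values measure the spread between these libraries. Estimated reads per library ranged from 10551751 to 17643018, with a median of 13673705, and 19071 genes were tested. The common biological coefficient of variation between libraries of a group was 0.317. Samples are named by group and replicate number, and values are means ± SD of normalized CPM, reads scaled to a common library size, over 4 libraries, or log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The test itself gives no SE. It was taken as the absolute log2 fold change divided by the square root of the F value, and is approximate.

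The healthy libraries differed from one another in tissue makeup. Skeletal muscle genes had a mean log2 CPM of 9.04 in HC 4 and 5.73 in HC 2, and of 1.74 to 2.54 in the other 10 libraries. Adipocyte genes had a mean log2 CPM of 5.76 in HC 2 and 5.54 in HC 4, and of 3.01 to 4.05 in the other libraries. Antimicrobial peptide genes had a mean log2 CPM of 5.402 in HC 4 and of 1.63 to 3.02 in the other 3 HC libraries. On the first principal component of the 500 most variable genes, which held 31.0% of the variance, HC libraries lay between -57.67 and -11.96, CPUO libraries between -5.39 and 27.26 and AD libraries between 12.71 and 30.86. These positions were described and not tested.

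**Figure D1:**
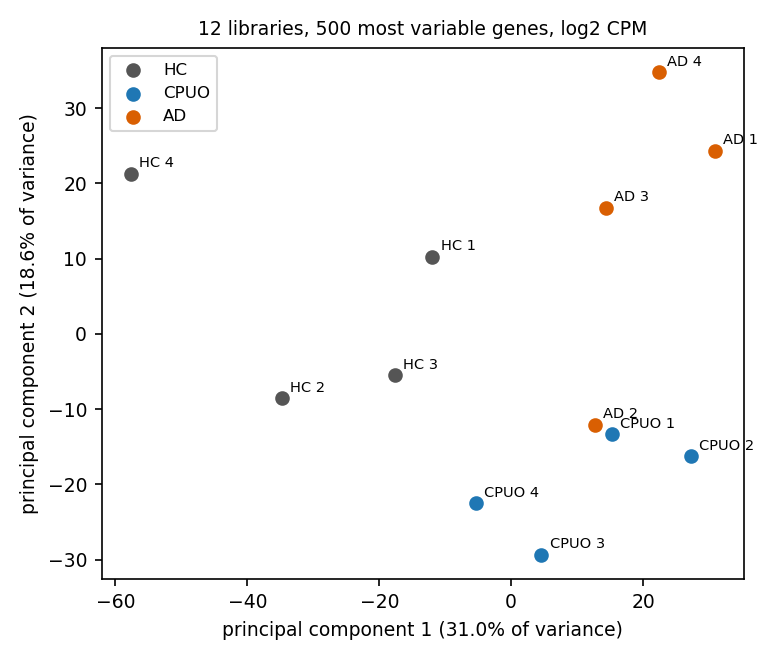
Positions of the 12 libraries on the first and second principal components of log2 CPM of the 500 most variable genes, 1 point per library, coloured by group. The 4 HC libraries lie at -11.96 or below on the first component, with HC 4 farthest out at -57.67, and AD 2 lies apart from the other 3 AD libraries on the second component, at -12.06.

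The first comparison asked how skin with CPUO differs from healthy skin. Among the genes that passed, some of keratinocytes and of cell division were higher in CPUO skin, and some of mast cells, macrophages and hair follicles and of the NR4A immediate early family were lower. As whole lists 0 of 43 passed by camera with an estimated correlation or by fry's directional test, beside 3 and 10 at an unadjusted p under 0.05. By camera with a preset correlation 23 did, and by fry's mixed test, which takes either direction, 25. KRT5, the keratin of basal keratinocytes (ENSG00000186081, GRCh38 chromosome 12, 52514575 to 52520687), rose from 3727 ± 509 CPM in HC to 9178 ± 1850 CPM in CPUO, a 2.46-fold difference (adjusted p = 0.0149). KRT10, a keratin of the layers above (ENSG00000186395, chromosome 17, 40818117 to 40822595), rose 2.83-fold, from 2398 ± 582 to 6790 ± 1736 CPM (adjusted p = 0.0162). CPA3, a mast cell protease (ENSG00000163751, chromosome 3, 148865256 to 148897196), fell 8.46-fold, from 23.4 ± 7.09 to 2.79 ± 1.48 CPM (adjusted p = 0.0184). Of 19071 genes, 784 passed the test at an adjusted p under 0.05, 365 higher and 419 lower in CPUO. Over all genes tested, the ranges of the 4 CPUO and 4 HC libraries did not overlap in 2955, or 15.5%, where chance gives 2.86%.

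Among 14 tested marker genes of basal keratinocytes, 5 rose and 0 fell, and 7 rose and 1 fell when adjusted over the list alone. KRT14, the partner of KRT5, had a log2 fold change of 1.18 ± 0.25, and ITGB4, a hemidesmosome integrin, of 1.62 ± 0.30. The cell cycle list had 10 of 35 members higher and 0 lower, 32 higher when adjusted over the list alone, and all 35 fold changes lay above 0, with a median log2 fold change of 0.86. Its members MKI67 (1.35 ± 0.31), a proliferation marker, and ANLN (1.57 ± 0.31) and KIF11 (0.83 ± 0.18), needed for cytokinesis and the spindle, rose. In the terminal differentiation list 3 of 37 members rose (also 3 when adjusted over the list alone). These were KRT10, KRT1 (1.07 ± 0.27) and KPRP (1.55 ± 0.38). Junction genes rose in 3 of 17 members (4 when adjusted over the list alone), among them the cornified envelope proteins PPL (1.18 ± 0.23) and EVPL (1.33 ± 0.27). Among 15 water and ion channel genes 3 rose (4 rose and 1 fell when adjusted over the list alone). They were the chloride channel ANO1 (1.83 ± 0.21), carbonic anhydrase CA12 (0.80 ± 0.15) and the sodium channel subunit SCNN1A (0.58 ± 0.11). The mean log2 CPM of the basal keratinocyte list was 7.91 to 8.38 in HC and 8.68 to 9.18 in CPUO, so this level moved with these gene groups. The cell cycle level minus the basal keratinocyte level differed by 0.168 log2 units, CPUO minus HC (exact permutation p = 0.514, adjusted p = 0.617). That test was not among those fixed beforehand. A rise of cell cycle genes beyond the basal keratinocyte level was thus not shown.

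Mast cell genes fell in 8 of 14 members, 11 when adjusted over the list alone, with a median log2 fold change of -1.46. Besides CPA3 they include the granule proteases TPSAB1 (-2.72 ± 0.50; its reads are shared with the near-identical TPSB2) and CTSG (-2.70 ± 0.56), and HPGDS (-1.55 ± 0.34), which makes prostaglandin D2. Macrophage genes fell in 4 of 19 members (11 when adjusted over the list alone). CD14 had a log2 fold change of -2.54 ± 0.46, the complement gene C1QA of -2.97 ± 0.63, FOLR2 of -3.28 ± 0.73 and the scavenger receptor MSR1 of -1.24 ± 0.31. Endothelial genes fell in 3 of 20 members (10 when adjusted over the list alone). They include the junction gene CLDN5 (-1.88 ± 0.30) and MMRN1 (-2.32 ± 0.42). Among 20 fibroblast genes 3 fell and 1 rose (6 and 1 when adjusted over the list alone). The list's median log2 fold change was -0.83, and 0.20 without HC 1. DPT (-2.40 ± 0.43) and MFAP4 (-1.83 ± 0.33), proteins of the dermal matrix, and the secreted WNT inhibitor WIF1 (-2.77 ± 0.69) fell, and APCDD1 (0.99 ± 0.25) rose. Matrix remodelling genes fell in 4 of 22 members (5 when adjusted over the list alone), among them the proteases ADAMTS4 (-1.66 ± 0.26) and ADAMTS1 (-1.43 ± 0.24) and the protease inhibitor TIMP3 (-1.44 ± 0.25). Of the antimicrobial peptide genes 0 of 23 passed by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, beside 6 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. Their median log2 fold change was -1.80, with 2 of 23 above 0, but -0.15 without HC 4 and -0.043 without HC 2 and HC 4.

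The orphan nuclear receptors NR4A3 (-3.79 ± 0.51), NR4A2 (-3.27 ± 0.60) and NR4A1 (-2.71 ± 0.66), which are switched on within minutes of a stimulus, and MYC (-1.22 ± 0.30) fell. Without CPUO 3, NR4A2 was at -3.88 and NR4A1 at -3.74. These were the 4 of 28 members of the immediate early list that passed (6 fell and 1 rose when adjusted over the list alone). BHLHE40, a stress-responsive repressor of the clock (ENSG00000134107, chromosome 3, 4979116 to 4985323), fell from 225 ± 38.9 to 81.8 ± 10.6 CPM and was the only 1 of 16 circadian genes to pass, also when adjusted over the list alone. Among 17 type 2 cytokine and receptor genes, GATA3, a transcription factor of type 2 lymphocytes and of keratinocytes, rose (1.70 ± 0.38) and IL1RL1, the receptor of IL-33, fell (-1.82 ± 0.33). On this list 1 rose and 2 fell when adjusted over the list alone. IL33 itself had a log2 fold change of -0.98 ± 0.31 (adjusted p = 0.0926). Of 40 itch mediator and receptor genes the leukotriene receptor LTB4R rose (0.72 ± 0.12), and HDC, which makes histamine (-2.06 ± 0.48), EDN1 (-1.72 ± 0.35) and its receptor EDNRA (-1.07 ± 0.20) fell. There were 3 higher and 7 lower when adjusted over the list alone. Of 18 neurotrophin and neuropeptide genes NGFR (1.57 ± 0.37), a receptor of neurotrophins, and the ligand NRTN (1.47 ± 0.32) rose. GFRA1 (-1.74 ± 0.21), a receptor of glial cell line derived factors, and NRP1 (-0.90 ± 0.16) fell, and there were 3 higher and 5 lower when adjusted over the list alone.

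Hair follicle genes fell in 6 of 27 members (17 when adjusted over the list alone), and hair shaft genes stood high among the largest decreases. Counted here are genes that passed, averaged at least 1 CPM, carried a symbol and had group ranges that did not overlap, of which the 10 with the largest decrease and the 10 with the largest increase are named. KRT33B (-7.18), KRTAP1-3 (-6.69), KRTAP4-3 (-6.37), KRTAP1-1 (-6.19), KRTAP4-2 (-6.19), KRT83 (-5.89), KRTAP1-5 (-5.79) and KRTAP4-4 (-5.78), given as log2 fold changes, were all under 1 CPM on average in CPUO, and the copies of these families share reads. Without HC 4 they were at -6.06, -5.33, -5.19, -4.59, -4.70, -4.01, -4.20 and -4.30 in the same order, and KRTAP4-2 and KRT83 did not pass. Without CPUO 4 KRT33B was at -9.49, KRTAP1-3 at -7.67, KRTAP4-2 at -7.01, where it did not pass, and KRTAP1-5 at -6.65. The readthrough gene BLOC1S5-TXNDC5 had no reads in CPUO and a mean of 8.90 CPM in HC, at least 158.5-fold lower against a floor of 3 counts over the 4 CPUO libraries. OVCA2 fell by 6.30 on the log2 scale, and both genes overlap other genes and are uncertain. Without HC 4 OVCA2 was at -5.39 and without CPUO 1 at -8.61, and it passed in neither. The other CPUO libraries had no reads of OVCA2, so -8.61 is not a measured fold. Skeletal muscle genes fell in 5 of 13 members (11 when adjusted over the list alone), where MYH2 reached 1937 CPM in HC 4 and 209 in HC 2 and 2.95 and 1.92 in the other HC libraries. Its log2 fold change was -4.76 without HC 4 and 0.09 without HC 2 and HC 4. By the same rule the largest increases were those of SYT8 (3.51 ± 0.60), C17orf50 (3.27 ± 0.63), CACNA1H (2.65 ± 0.56), SP8 (2.46 ± 0.57), CA2 (2.37 ± 0.59), HOXB3 (2.35 ± 0.50), WNT7A (2.31 ± 0.46), WNT7B (2.28 ± 0.49) and RTN4RL2 (2.23 ± 0.49). CA2 was at 1.55 and did not pass without CPUO 2, SP8 was at 3.35 without HC 1 and C17orf50 at 3.94 without HC 3. Among these genes are a T-type calcium channel (CACNA1H), a transcription factor of the HOX clusters (HOXB3) and epidermal WNT ligands (WNT7A, WNT7B). MTND1P23, a pseudogene of the mitochondrial MT-ND1 which shares reads with it, had a fitted log2 fold change of 5.86 ± 1.17, 6.64 without HC 1, and its value turned to -0.067 in the gene CPM matrix with no filter.

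The size of this difference moved with most single libraries. The number of genes passing was 100 without CPUO 1, 101 without CPUO 3, 320 without CPUO 4, 370 without HC 1, 234 without HC 2, 343 without HC 4 and 1178 without AD 4. It was 74 without both HC 2 and HC 4, a choice made after seeing the data, and 428 with a term for the replicate number. The balance of directions moved too, to 64 higher and 170 lower without HC 2, 125 and 218 without HC 4, 147 and 223 without HC 1, and 5 and 69 without HC 2 and HC 4. Of the 67 genes named here that passed, 10 also passed in every fit without 1 library (KRT5, KRT10, ANO1, LTB4R, GFRA1, BHLHE40, NR4A3, CLDN5, ADAMTS4 and KRTAP4-3). Of the 67, 55 were lost without CPUO 1, 53 without CPUO 3, 33 without HC 2, 27 without HC 4, 25 without HC 1, 25 without CPUO 4, 14 without CPUO 2, 10 without HC 3, 13 without AD 3, 8 without AD 1 and 7 without AD 2. By camera with a preset correlation, 23 of 43 gene lists passed, 7 upward and 16 downward. The cell cycle, mast cell and macrophage lists had an adjusted p = 0.649 with an estimated correlation. By limma-trend on the gene CPM matrix, run without TMM factors, 34.5% of calls were upward, against 46.6% here.

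**Figure D2:**
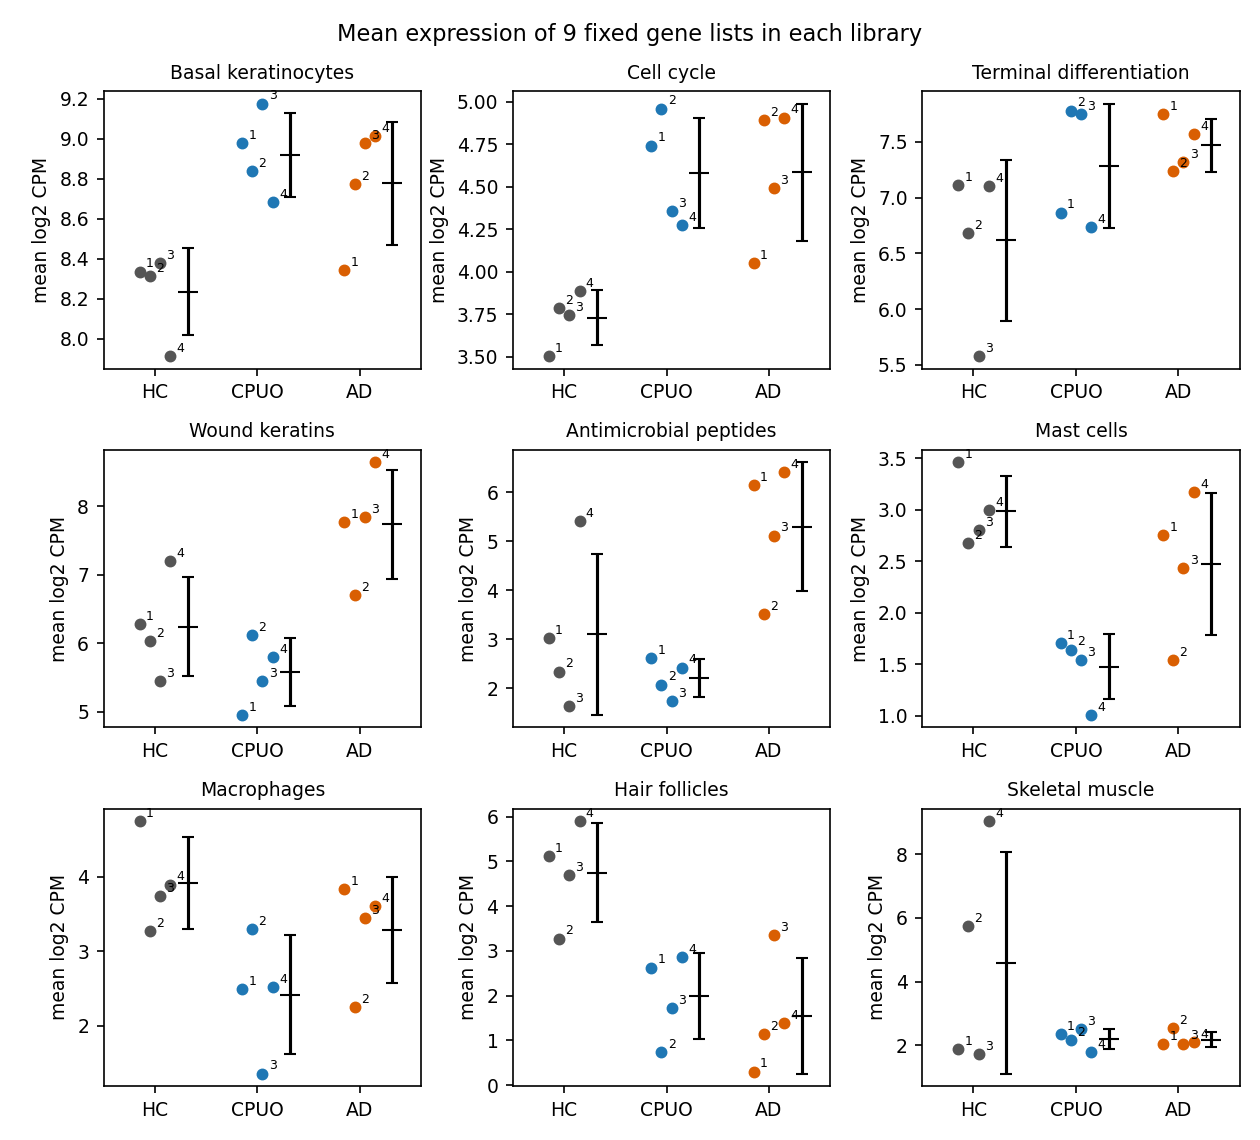
Mean log2 CPM of the members of 9 fixed gene lists in each of the 12 libraries, 1 point per library with its replicate number, and beside them the group mean with the SD of 4 libraries. Mast cell genes lay between 1.01 and 1.71 in CPUO and between 2.68 and 3.46 in HC, basal keratinocyte genes between 8.68 and 9.18 in CPUO and between 7.91 and 8.38 in HC, and skeletal muscle genes stood out in HC 2 and HC 4.

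The second comparison asked how AD skin differs from healthy skin. Among the genes that passed, AD skin had higher levels of some keratins of basal, suprabasal and wounded epidermis, of beta defensins, of some cell division genes and of receptors of interleukin 4 and histamine, and lower levels of some hair follicle and NR4A genes. As whole lists 0 of 43 passed by camera with an estimated correlation or by fry's directional test, beside 3 and 11 at an unadjusted p under 0.05. By camera with a preset correlation 17 did, and by fry's mixed test 21. KRT6A, a keratin of wounded and hyperproliferative epidermis (ENSG00000205420, chromosome 12, 52487174 to 52493257), rose 12.1-fold, from 811 ± 427 CPM in HC to 9786 ± 4996 CPM in AD (adjusted p = 0.0305), with reads shared among the KRT6 copies. IL4R, the receptor chain shared by IL-4 and IL-13 (ENSG00000077238, chromosome 16, 27313668 to 27364778), rose 1.97-fold, from 57.4 ± 9.38 to 113 ± 34.5 CPM (adjusted p = 0.0306). The histamine receptor HRH1 (ENSG00000196639, chromosome 3, 11137093 to 11263557) rose 2.86-fold, from 18.7 ± 2.48 to 53.6 ± 26.8 CPM (adjusted p = 0.0201). Of 19071 genes, 1186 passed, 659 higher and 527 lower in AD. This balance turned to 347 higher and 432 lower without HC 1, 147 and 173 without HC 2, and 337 and 410 without HC 3. Over all genes tested, group ranges did not overlap in 2506, or 13.1%, where chance gives 2.86%.

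Among 21 wound keratin and hyperproliferation genes 3 rose, KRT6A (3.59 ± 0.82), KRT6C (4.71 ± 1.26) and SPRR2G (3.33 ± 0.85), and 11 rose and 1 fell when adjusted over the list alone. KRT16, the partner of KRT6, had 474 ± 316 CPM in HC and 5881 ± 3227 in AD and an adjusted p of 0.0511. Of 23 antimicrobial peptide and alarmin genes 2 rose, the beta defensin genes DEFB4B (5.65 ± 1.23) and DEFB103A (4.44 ± 1.01), which have near-identical copies, and 2 rose and 1 fell when adjusted over the list alone. S100A7 (1.66 ± 1.01, adjusted p = 0.347), S100A8 (1.84 ± 1.08, 0.331) and S100A9 (1.67 ± 1.13, 0.407) did not pass, and HC 4 held 1074 CPM of S100A8 where the other HC libraries held 77.8, 39.7 and 44.6. Without HC 4 all 3 passed, at 4.26, 4.37 and 4.41, and SPRR2G was at 4.39 and DEFB4B at 7.90. DEFB4B was at 4.18 without AD 1, and DEFB103A was at 3.66 and did not pass without AD 4. Basal keratinocyte genes rose in 5 and fell in 1 of 14 members (7 and 2 when adjusted over the list alone). KRT14 (1.90 ± 0.26), KRT5 (1.504 ± 0.22) and ITGA6 (1.13 ± 0.24) rose and KRT15 (-2.27 ± 0.39), a keratin of resting basal cells and of the hair bulge, fell. The list's mean log2 CPM was 8.34 to 9.01 in AD, above every HC library except that AD 1, at 8.34, lay within the HC range. Terminal differentiation genes rose in 8 of 37 members (14 rose and 1 fell when adjusted over the list alone). KRT10 had a log2 fold change of 1.56 ± 0.25, the desmosome cadherin DSG1 of 1.27 ± 0.24, KPRP of 1.98 ± 0.38 and the crosslinking enzyme TGM3 of 2.28 ± 0.45. FLG, the filaggrin gene, had a log2 fold change of 0.21 ± 0.43 and IVL, involucrin, of 1.18 ± 0.58, and neither passed (adjusted p = 0.824 and 0.238). IVL was at 1.87 without HC 4. FLG turned to -0.0314 without HC 3, -0.41 without AD 1 and -0.0714 in the gene CPM matrix.

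Junction genes rose in 4 of 17 members (5 when adjusted over the list alone), with PPL at 1.23 ± 0.23 and the cadherin CDH1 at 0.74 ± 0.15. Of 25 barrier lipid genes 2 rose (5 when adjusted over the list alone), the lipoxygenases ALOX12B (1.74 ± 0.38, 2.33 without HC 4) and ALOXE3 (1.02 ± 0.27). Water and ion channel genes rose in 4 of 15 members (5 rose and 1 fell when adjusted over the list alone), among them AQP3, the aquaporin of keratinocytes (1.91 ± 0.38), ANO1 (1.64 ± 0.21) and SCNN1A (1.18 ± 0.12). Cell cycle genes rose in 16 of 35 members (34 when adjusted over the list alone). Among them were RRM2, which supplies deoxynucleotides, at 1.47 ± 0.25, ANLN at 1.62 ± 0.31, NCAPG at 1.11 ± 0.22 and the replication helicase subunit MCM5 at 0.83 ± 0.17. The cell cycle level minus the basal keratinocyte level differed by 0.311 log2 units, AD minus HC (exact permutation p = 0.2, adjusted p = 0.4). A rise beyond the basal keratinocyte level was thus not shown here either. Replication-dependent histone genes, whose members share sequence, rose in 5 of 16 (12 when adjusted over the list alone), with H2AC4 at 1.71 ± 0.34, H1-5 at 1.45 ± 0.32 and H2AC12 at 1.48 ± 0.33. AD 4 had a mean log2 CPM of 6.38 for them where the other AD libraries had 5.18 to 5.28. IL4R was the only 1 of 17 type 2 cytokine and receptor genes to pass, also when adjusted over the list alone. Of 40 itch mediator and receptor genes 4 rose and 1 fell (8 and 2 when adjusted over the list alone), among them HRH1 (1.52 ± 0.31), LTB4R (1.23 ± 0.12) and LPAR5 (1.03 ± 0.22), a receptor of lysophosphatidic acid. Among 18 neurotrophin and neuropeptide genes NRTN rose (1.92 ± 0.32) and GFRA1 fell (-1.88 ± 0.21), with 2 higher and 3 lower when adjusted over the list alone.

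NR4A3 (-3.12 ± 0.49), NR4A1 (-2.63 ± 0.66) and CCN1 (-2.34 ± 0.52) fell, among 5 of 28 immediate early genes that did (also 5 when adjusted over the list alone). Matrix remodelling genes fell in 4 of 22 members, ADAMTS1 among them (-1.49 ± 0.24), with 3 higher and 4 lower when adjusted over the list alone. DPT (-2.16 ± 0.43) was the 1 of 20 fibroblast genes and CLDN5 (-1.58 ± 0.29) the 1 of 20 endothelial genes to fall. When adjusted over each list alone, 2 fibroblast genes fell and 1 rose, and 1 endothelial gene fell. Of 14 mast cell genes 1 fell, the amine transporter SLC18A2 (-0.86 ± 0.21; also 1 when adjusted over the list alone), while CPA3 (-0.85 ± 0.51, adjusted p = 0.339) and TPSAB1 (-0.53 ± 0.47, 0.544) did not pass. No macrophage gene of 19 passed by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, beside 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Hair follicle genes fell in 7 of 27 members (21 when adjusted over the list alone), with KRT26 at -4.26 ± 0.72 and KRT33B at -6.20 ± 1.31. Without HC 4 they were at -3.27 and -5.06, and without AD 3 KRT33B was at -6.84 and did not pass. By the rule used for CPUO, 9 of the 10 largest decreases were in keratin associated proteins: KRTAP7-1 (-8.22), KRTAP1-1 (-6.92), KRTAP9-8 (-6.64), KRTAP4-12 (-6.59), KRTAP8-1 (-6.34), KRTAP19-3 (-6.34), KRTAP4-2 (-6.33) and KRTAP4-3 (-6.22) and KRTAP19-5. Without HC 4 the first 8 were at -7.39, -5.30, -5.30, -5.33, -5.46, -5.31, -4.82 and -5.01 in the same order. KRTAP4-2 was at -7.38 without AD 3 and KRTAP4-3 at -6.88 without AD 4. KRTAP7-1 was at -9.78 without AD 1 and KRTAP19-3 at -8.64 without AD 3. The AD libraries left in those fits had no reads of KRTAP7-1 and KRTAP19-3 respectively, so both values are not measured folds. AD 1 held 0.0649 CPM of KRTAP7-1 and AD 3 0.135 CPM of KRTAP19-3. KRTAP19-5 had no reads in AD and was at least 65.0-fold lower against a floor of 3 counts over the 4 AD libraries. The 10th was SLN (-6.86), a muscle gene at 46.3 CPM in HC 4, and at -4.66 without that library. Skeletal muscle genes fell in 8 of 13 members (11 when adjusted over the list alone), with MYH2 at -7.19 and TTN at -4.97. Without HC 4 they were at -4.27 and -2.23 and did not pass, and without HC 2 and HC 4 the value of MYH2 turned to 0.58. The adipocyte list had 1 of 14 members lower, CFD (-0.997 ± 0.25), and 4 when adjusted over the list alone.

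By that rule the largest increases, besides DEFB4B, KRT6A, KRT6C and SPRR2G, were those of SH2D5 (4.24 ± 0.78), CXCR1, the interleukin 8 receptor of neutrophils (3.60 ± 0.64), CA2 (3.35 ± 0.61), NFE2 (2.53 ± 0.46), SLURP2 (2.4996 ± 0.41), which overlaps other transcripts, and WNT7A (2.49 ± 0.46). Without AD 4 SH2D5 was at 3.11 and CA2 at 2.65. CXCR1 was the only 1 of 9 neutrophil genes to pass, also when adjusted over the list alone. The number of genes passing was 779 without HC 1, 320 without HC 2, 747 without HC 3, 669 without AD 2, 333 without AD 3 and 480 without AD 4, 254 without both HC 2 and HC 4, and 743 with a term for the replicate number. With that term IL4R, KRT6C, DEFB103A, ALOXE3, NR4A1, SLC18A2, MYH2 and TTN, of the genes named, did not pass, IL4R with an adjusted p of 0.0527. Of the 61 named genes that passed, 32 also passed in every fit without 1 library. The most were lost without HC 2 (23), AD 3 (22), AD 4 (19) and AD 2 (14). Fewer were lost without HC 1 (12), HC 3 (12), AD 1 (7), HC 4 (5), CPUO 4 (7), CPUO 3 (6), CPUO 2 (4) and CPUO 1 (3). By limma-trend on the gene CPM matrix, run without TMM factors, 24.5% of calls were upward, against 55.6% here. The median of all genes was then shifted by -0.19 on the log2 scale. By edgeR with TMM on reads recovered from that matrix 54.0% were upward, with a shift of 0.0086. By camera with a preset correlation 17 of 43 lists passed, 11 upward and 6 downward. The lists of the cell cycle and of wound keratins had an adjusted p = 0.649 with an estimated correlation.

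**Figure D3:**
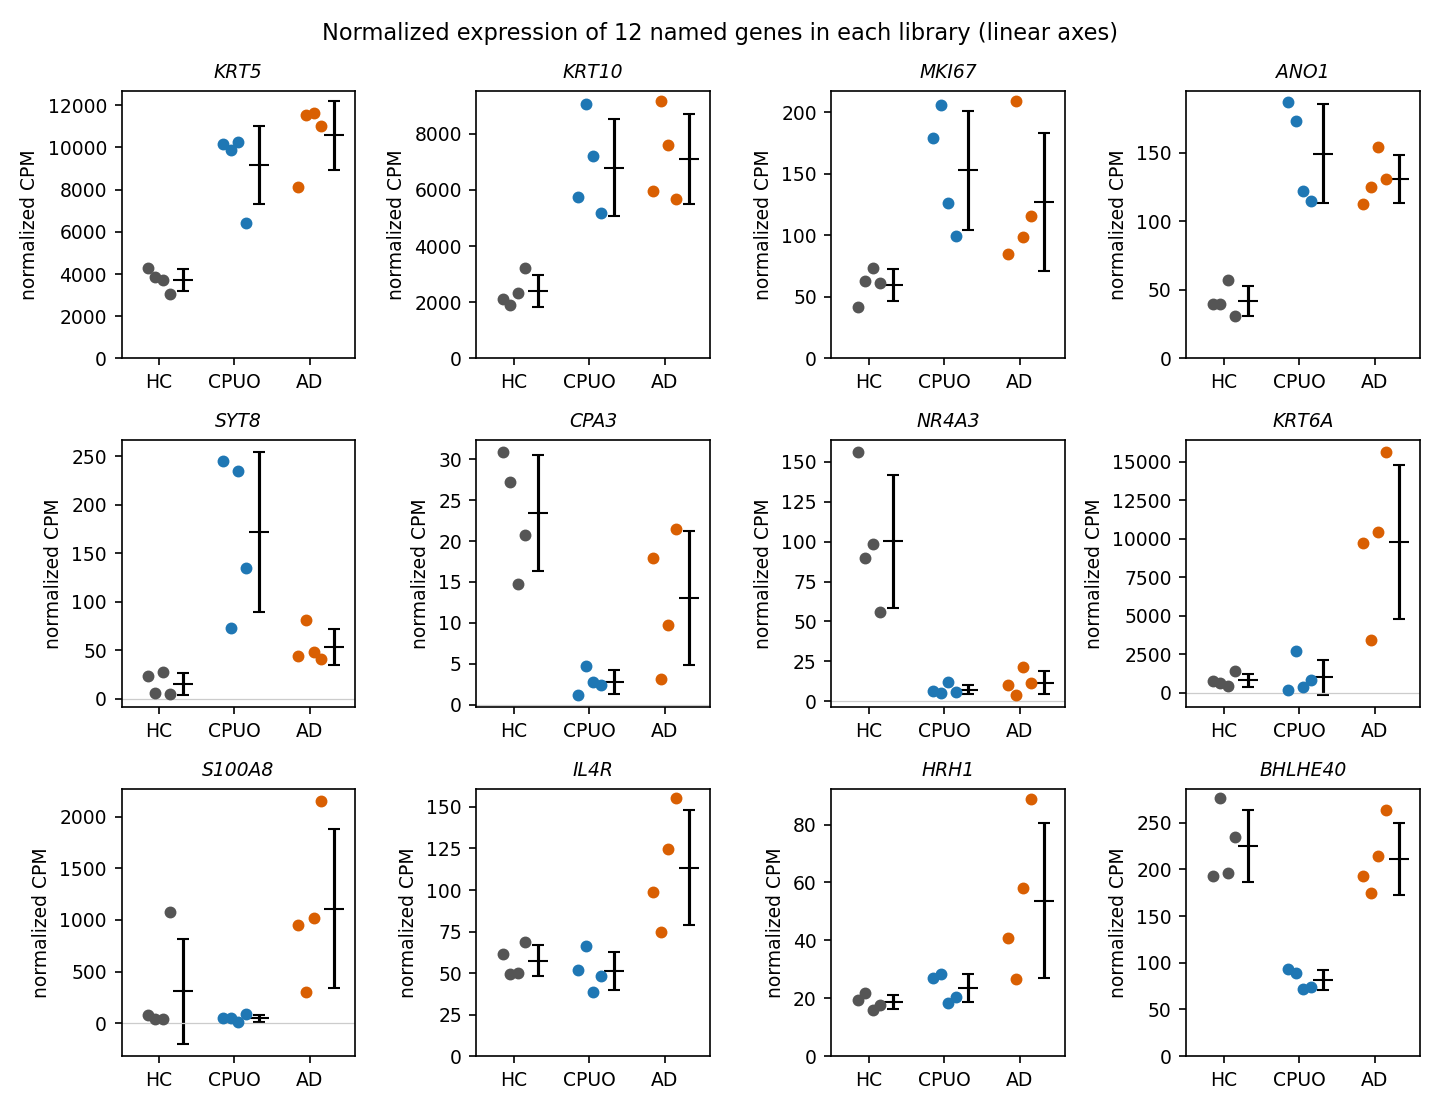
Normalized CPM of 12 named genes in each library on linear axes, 1 point per library, with the mean and SD of each group of 4 beside them. KRT5, KRT10, MKI67 and ANO1 lay above all HC libraries in both diseases, IL4R and KRT6A above all HC libraries in AD, and BHLHE40 lay between 71.6 and 92.8 CPM in CPUO and at 174 CPM or more in every HC and AD library.

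The third comparison tested directly whether AD and CPUO skin differ. BHLHE40 was higher in AD than in CPUO, with 81.8 ± 10.6 CPM in CPUO and 211 ± 38.2 CPM in AD (log2 fold change 1.37 ± 0.17, adjusted p = 0.0277). Its level in HC, given in the first comparison, was also above that in CPUO, so this is no rise over healthy skin. PSG4 (-3.21 ± 0.39, adjusted p = 0.0277; ENSG00000243137, chromosome 19, 43192702 to 43207299) and PSG9 (-2.28 ± 0.30, 0.0323), carcinoembryonic antigen family members whose near-identical neighbours share reads, and SCCPDH (-1.32 ± 0.18, 0.0450; ENSG00000143653, chromosome 1, 246724047 to 246768137) fell. These were the 4 genes of 19071 to pass, beside 3447 at an unadjusted p under 0.05, 654 passing by DESeq2 and 2 by limma-voom. Genes of inflamed epidermis had higher values in AD that did not pass. S100A8 had 48.8 ± 33.3 CPM in CPUO and 1108 ± 769 in AD (log2 fold change 4.50 ± 1.21, adjusted p = 0.166).

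Over 23 antimicrobial peptide and alarmin genes the median log2 fold change was 3.82, and 22 lay above 0. By edgeR's test 0 passed over all genes and 18 when adjusted over the list alone (camera adjusted p = 1.11e-14, and adjusted p = 0.649 with an estimated correlation). Its members S100A9 (4.61 ± 1.28), S100A7 (3.82 ± 1.10), DEFB4B (6.76 ± 1.35) and DEFB103A (5.47 ± 1.10) had adjusted p between 0.135 and 0.178. DEFB4B was at 5.29 without AD 1, and DEFB103A at 6.07 without CPUO 3 and 4.69 without AD 4. Over 21 wound keratin and hyperproliferation genes the median was 2.33, and 19 lay above 0. By the same test 0 passed over all genes and 19 when adjusted over the list alone (camera adjusted p = 3.96e-15, and adjusted p = 0.649 with an estimated correlation). On the antimicrobial list there were 18 at an unadjusted p under 0.05, 13 by DESeq2 and 0 by limma-voom, and on the wound keratin list 19 at an unadjusted p under 0.05, 13 by DESeq2 and 0 by limma-voom. KRT6B had a log2 fold change of 3.39 ± 0.70, SPRR1A of 3.31 ± 0.66, SPRR1B of 3.22 ± 0.68 and KRT16 of 2.98 ± 0.96, which was 4.83 without CPUO 2. Mast cell genes had a median of 1.12 over 14 members, with 0 passing over all genes and 8 when adjusted over the list alone (adjusted p = 0.649 with an estimated correlation), beside 9 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma-voom. Endothelial genes had a median of 0.60, 20 of 20 above 0, which was 0.39 without AD 3. Macrophage genes had a median of 0.85, 17 of 19 above 0, which was 0.56 without CPUO 3 and 1.36 without CPUO 2. The mast cell level minus the mean of the fibroblast and endothelial levels differed by 0.477 log2 units, AD minus CPUO (exact permutation p = 0.257, adjusted p = 0.45). CPA3 had a log2 fold change of 2.23 ± 0.55, TPSAB1 of 2.19 ± 0.50 and CTSG of 2.32 ± 0.56. IL4R (1.15 ± 0.23, adjusted p = 0.135), TSLP (1.47 ± 0.44, 0.183), an epithelial cytokine of type 2 inflammation, HRH1 (1.19 ± 0.30, 0.158) and AQP3 (1.17 ± 0.37, 0.194) did not pass. IVL had a log2 fold change of 2.40 ± 0.60, LORICRIN of -1.12 ± 0.43 and the tight junction gene CLDN1 of -0.75 ± 0.25, with adjusted p between 0.155 and 0.227. Of the genes with the smallest p after those that passed, CACNA1H (-3.32) and SCEL (-1.14) had lower and RNF145 (0.87), RALGPS2 (0.88), PYGL (0.999) and TPBG (1.02) higher values in AD, each with an adjusted p of 0.135. Cell cycle genes had a median log2 fold change of 0.03, from -0.104 without CPUO 4 to 0.208 without AD 1, and 0 of 35 passed by edgeR, over all genes or adjusted over the list alone, beside 2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom.

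Without AD 2 the number of genes passing was 79, 60 of them higher in AD, and 4 members of the antimicrobial and wound keratin lists passed. It was 2 without HC 2, 1 without AD 1, and 0 by edgeR without HC 3, HC 4, CPUO 1, CPUO 3, CPUO 4, AD 3 or AD 4, where 1924 to 3484 genes had an unadjusted p under 0.05. Without CPUO 2 it stayed at 4 but kept 2 of the 4 genes. By edgeR it was also 0 with a term for the replicate number and with only the 2 groups compared, where 3443 and 3249 genes had an unadjusted p under 0.05. By camera with a preset correlation 20 of 43 lists passed, 19 upward and 1 downward, and 0 did with an estimated correlation or by fry's directional test, beside 2 and 3 at an unadjusted p under 0.05, and 15 did by fry's mixed test.

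Whether the 2 diseases changed the same genes was asked by setting their fold changes against HC side by side. Of the genes passing in both comparisons, 178 were higher in both diseases and 219 lower in both, and 0 went opposite ways. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.657 (jackknife SE over libraries 0.135) and Spearman's rho 0.554, and r was 0.505 on average in 20 simulations of unchanged groups that shared the 4 controls. The covariance was 0.360, and 0.0837 in the simulations, a difference of 0.277. The simulations gave each gene the same spread in every group. HC libraries had a mean Spearman correlation with one another of 0.955, against 0.970 in CPUO and 0.965 in AD. The simulations may therefore understate what shared controls add to r and to the covariance. With 2 controls for CPUO and the other 2 for AD, r was 0.361 on average, 0.193 to 0.501 over 6 assignments, with a covariance of 0.133 to 0.291, and 2 to 32 shared genes higher and 8 to 71 lower. With HC 2 and HC 4 as the controls of CPUO there were 32 higher, 71 lower and 10 opposite, and the other 5 assignments had 2 to 11 higher, 8 to 36 lower and 0 opposite.

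**Figure D4:**
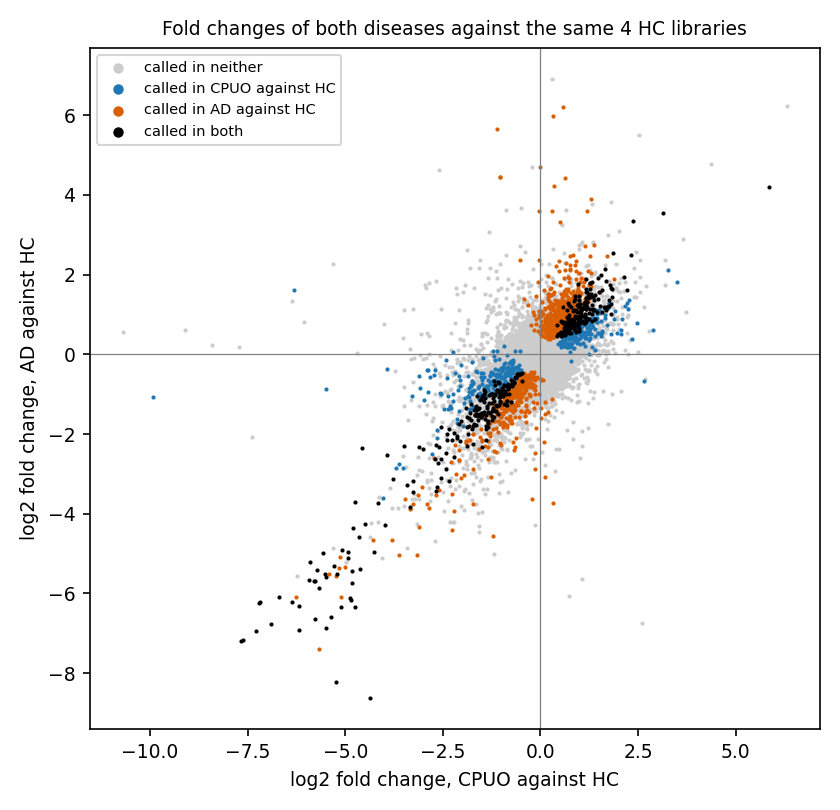
Log2 fold change of each of 19071 genes in CPUO against HC on the horizontal axis and in AD against HC on the vertical axis, 1 point per gene, coloured by the comparison in which it passed. The 178 genes higher and the 219 genes lower in both lie in the upper right and lower left. Both axes use the same 4 HC libraries, which by itself gave r = 0.505 in simulations with the same spread in every group.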

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

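Tests chosen only after the result was seen were those of the share of epidermis, the lower share of dermis, the tryptase copies and the spread from AD 2, and the fits without HC 2 and HC 4 and on recovered reads were also chosen then. Among 517 groups of 4 libraries, 47 had a library standing far from the other 3 by Dixon's test at its 95% critical value, where chance gives about 1 in 20, or 25.9, for normally distributed values. HC 4 held 11 of these. Gene values were tested as CPM, which need not be normally distributed. OVCA2 in CPUO 1, KRTAP7-1 in AD 1 and KRTAP19-3 in AD 3 were counted because the other 3 libraries had no reads. The number above 25.9 is therefore no measure of an excess. No biological explanation was tested for single libraries.

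HC 4 stood above the other HC libraries in CPM of S100A7 (1875), S100A8 (1074), S100A9 (2192), IVL (291), DEFB4B (1.27), KRT83 (148), MYH2 (1937), SLN (46.3) and TTN (24837). HC 4 stood below the other HC libraries in mean log2 CPM of epidermal junction genes (5.93) and of basal keratinocyte genes (7.91). HC 1 stood apart in CPM of KIF11 (16.7, lower) and C1QA (43.2, higher) and in the mean log2 CPM of itch genes (3.95, higher), and HC 3 in that of erythrocyte genes (1.52, lower).

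CPUO 1 stood above the other CPUO libraries in CPM of HOXB3 (25.9), SCNN1A (106), OVCA2 (0.131), SLURP2 (38.2) and TGM3 (154). CPUO 2 did so in CPM of CA2 (249), CLDN5 (10.2), KRT6C (214), KRT16 (2360) and SCCPDH (26.5), and it lay below them in KRT15 (283). CPUO 3 stood above them in CPM of HPGDS (2.81), NR4A1 (168) and NR4A3 (11.7) and in mean log2 CPM of plasma cell genes (2.80). CPUO 4 stood apart in CPM of KRT5 (6413, lower) and KRT33B (0.542, higher).

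AD 1 stood above the other AD libraries in CPM of FLG (21745) and KRTAP7-1 (0.0649), and below them in mean log2 CPM of neurotrophin and neuropeptide genes (2.66). AD 2 stood below the others in CPM of MFAP4 (19.5) and in mean log2 CPM of itch genes (3.53), and above them in that of skeletal muscle genes (2.54). AD 3 stood above them in CPM of ADAMTS4 (52.9), KRTAP4-2 (0.807) and KRTAP19-3 (0.135), and below them in NFE2 (3.97). AD 4 stood above the others in CPM of CA2 (464) and NRTN (9.24) and in mean log2 CPM of epidermal junction (6.59), erythrocyte (3.08) and histone genes (6.38).

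Many genes passed between each disease group and HC. Without HC 2 and HC 4 the median signed log2 fold change of the genes passing in CPUO against HC was 0.949 of its value, from 1.17 to 1.11. Of these genes, 782 of 784 kept their sign. They were chosen with all 4 HC libraries, and 744 of them had group ranges without overlap, which favours a kept sign and size. Their fold changes were thus also seen against HC 1 and HC 3. Whether muscle and fat in HC 2 and HC 4 added to the number passing stays open. The counts themselves fell to 74 and 254 with 2 fewer controls. The share of epidermis in the biopsy cannot be told apart from the disease in CPUO: with the basal keratinocyte level as covariate that median was 0.841 of its value, but every CPUO library lies above every HC library in that level, 8.68 at least against 8.38 at most. In AD, where AD 1 at 8.34 lies within the HC range, that ratio was 0.854 with 1186 of 1186 signs kept while 7 genes passed, so this share stays open there too, and so does the disease itself, which is untested.

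Mast cell genes were lower in CPUO than in HC. Reads shared between the tryptase copies are argued against, since the 11 members other than tryptases had a median log2 fold change of -1.55. A lower share of dermis may account for it in part: the mast cell level minus the mean of the fibroblast and endothelial levels differed by -0.69 log2 units, CPUO minus HC, with a two-sided exact permutation p of 0.0857, or 0.225 adjusted, so this stays open. A difference in mast cells between CPUO and healthy skin stays open and untested, and so does the tissue source of the samples, punch biopsy or surgery, which is not given per sample in the sources used here.

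For the 784 genes of CPUO against HC and, over all splits, the 1186 of AD against HC, 1 of 35 splits, the real one, gave as many. The highest other gave 4 and 2. A share of 1 of 35 is under 0.05 and is the smallest that these splits can give. The splits treat the 8 libraries as separate people, which the labels do not say. Between HC and CPUO, 2 of 4 pairs of libraries with the same number correlated over 0.1. HC and AD libraries with the same number correlated, and 8 splits part all 4 of these pairs, too few for a share under 0.05. Of these the real one gave 1186 genes and the highest other 0, and with a replicate block 743 and 0, where by edgeR without the block 349 to 1787 genes of the other 7 had an unadjusted p under 0.05. For gene lists as a whole chance division cannot be excluded in any comparison: 3 of 35 splits gave at least the 23 lists of CPUO against HC (highest other 25), 19 the 17 lists of AD against HC (highest other 24) and 12 the 20 lists of AD against CPUO (highest other 23).

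Antimicrobial and wound keratin genes had high fold changes in AD against CPUO while 4 genes passed in all. Of 35 splits 1, the real one, gave as many, and the highest other gave 1. At an unadjusted p under 0.05 by edgeR the real split had 3447 genes. The split that put AD 2 with CPUO 1, CPUO 3 and CPUO 4 had 3492, so chance division is not excluded here. The spread that AD 2 brings to AD is consistent with the low count: without AD 2, 79 genes passed. For the 2 lists as a whole, reads shared between copies are argued against. The median over the 41 of 44 members measured in both tables was 1.01 times as large in recovered reads as in transcript sums (2.69 and 2.65). It mixes members with and without near-identical copies, so it cannot decide for single copied genes such as the KRT6 and beta defensin genes. Why AD 2 differs from the other AD libraries was not tested, and the labels do not say whether the AD skin was lesional. Whether disease biology accounts for these fold changes stays open and untested.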

How the results depend on the processing

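Tests without HC 2 and HC 4, with the basal keratinocyte or fibroblast level as covariate, and on recovered reads were chosen after seeing the data. Of 68 named genes in CPUO against HC, 66 never changed sign in any alternative, of 69 in AD against HC 67 did not, and of 29 in AD against CPUO 29 did not. Apart from the preset genes, they were named for ranges without overlap or a small p in these same libraries, which favours a kept sign. The cause of the following shifts was not tested, except that fewer libraries or a covariate tied to the groups leave less to test with. The limma-trend fits also differed from the main fit in taking no TMM factors.

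In CPUO against HC the 784 genes became 499 with no low-count filter, 1882 by limma-voom with sample weights, and 2073 by DESeq2. They became 74 without HC 2 and HC 4, 9 with the basal keratinocyte level as covariate and 495 where an absolute log2 fold change of at least 1 was also required, and 100 to 1178 without 1 library. In AD against HC the 1186 genes became 476 with only the 2 groups compared, and 2433 by DESeq2. They became 254 without HC 2 and HC 4, 7 with the basal keratinocyte level as covariate and 666 with an absolute log2 fold change of at least 1, and 320 to 1117 without 1 library. In AD against CPUO the 4 genes became 2 with a transcript length offset, 2 by limma-voom, 15 with sample weights and 654 by DESeq2. By edgeR they became 0 with only the 2 groups compared, without HC 2 and HC 4 or with the basal keratinocyte level, where 3249, 3605 and 3178 genes had an unadjusted p under 0.05, and 0 to 79 without 1 library. With a replicate block, in a design the labels do not pair, the counts were 428, 743 and 0. Of 12 pairs of libraries with the same number 6 correlated above 0.1 (mean 0.042), 4 of 4 between HC and AD (0.172 to 0.209), 2 of 4 between HC and CPUO and 0 of 4 between CPUO and AD (-0.203 to -0.0181), with 5 of 12 libraries closest to one of their own number.

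By limma-trend on the CPM table the median of all genes shifted by -0.19 in AD against HC and -0.145 in AD against CPUO. By edgeR on reads recovered from it the shifts were 0.0086 and -0.0193. The limma-trend fits took no TMM factors, and the edgeR fit did. For the gene sums these factors were 0.804 to 0.986 in AD, 0.996 to 1.07 in CPUO and 0.965 to 1.16 in HC. Leaving them out lowers AD, which is the direction of the limma-trend shift. Lists passing by camera came to 0 in all 3 comparisons with an estimated correlation and 0 by fry's directional test, and to 15 in CPUO against HC with the basal keratinocyte level. In AD against CPUO they came to 13 on limma-voom values and 10 with the fibroblast level. The correlation of both disease effects was 0.361 with different controls for each disease.

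Log2 fold changes changed sign for MTND1P23 in CPUO against HC (-0.067 in the CPM table with no filter), and for MYH2 without HC 2 and HC 4 (0.09 in CPUO, 0.58 in AD). FLG in AD against HC did so too (-0.0714 in the CPM table with each pseudocount and with no filter, and -0.41 to 0.43 without 1 library). List tests that passed turned direction, medians in brackets, in CPUO against HC with the basal keratinocyte level for basal keratinocytes (0.0493, still above 0) and antimicrobial peptides (0.65), with the fibroblast level for fibroblasts (0.0866). Without HC 2 and HC 4 they did so for skeletal muscle (0.30, and 0.42 in AD against HC), sebaceous glands (1.15), adipocytes (0.0786) and the hypoxia response (0.0376). Medians alone changed sign in CPUO against HC for fibroblasts without HC 1 (0.20), wound keratins without HC 2 and HC 4 (0.13), junctions with the basal keratinocyte level (-0.15) and immediate early genes without HC 1 (0.0042), CPUO 1 (0.0424) or CPUO 4 (0.0114). In AD against HC they did so for adipocytes without HC 2 and HC 4 (0.0565). Immediate early genes there passed downward without HC 4 (-0.0871), AD 4 (-0.33) or HC 2 and HC 4 (-0.31), with the basal keratinocyte level (-0.75), and without CPUO 3, where the median was 0.005. Without 1 library the median of ribosomal proteins in AD against HC ranged from -0.20 to 0.19, passing upward without HC 2 (0.19), AD 3 (0.17) or HC 2 and HC 4 (0.36) and downward without AD 4 (-0.20), and of histones in AD against CPUO from 0.0429 to 0.50. At this depth and number of libraries a 2-fold change was recovered in 20% of simulated genes for CPUO against HC, where 200 genes were changed.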

Other observations

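Melanocyte genes had higher values in CPUO than in HC in 11 of 12 members, with a median log2 fold change of 1.56. This median was 0.89 without CPUO 1 and 0.52 with the basal keratinocyte level as covariate. The list's mean log2 CPM was 6.54 in CPUO 1 and 6.13 in CPUO 3. In CPUO 2 and CPUO 4 it lay within the HC range of 3.71 to 4.86, so the higher level was not shared by all CPUO libraries. By edgeR's quasi-likelihood test 0 passed over all genes and 5 when adjusted over the list alone, beside 8 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom, and the list had an adjusted p = 0.723 with an estimated correlation. Sebaceous gland genes had a mean log2 CPM of 7.59 in HC 2, 7.38 in HC 4, 6.44 in CPUO 4 and 5.77 in CPUO 3, and of 2.04 to 5.21 in the other libraries, and 0 of 20 passed by edgeR in AD against HC or in CPUO against HC, over all genes or adjusted over the list alone. In AD against HC there were 11 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom, and in CPUO against HC 2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom.

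In AD against CPUO, 48 of 48 ribosomal protein genes had values above 0, with a median log2 fold change of 0.38 (0.137 without AD 4), and 0 passed over all genes or adjusted over the list alone (adjusted p = 0.723 with an estimated correlation), beside 6 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The mean level was 9.31 in AD 4 and 8.35 to 8.55 in the other AD libraries. Hypoxia response genes had a median of 0.66, with 18 of 20 above 0, 0 passing over all genes and 3 when adjusted over the list alone (adjusted p = 0.684 with an estimated correlation), beside 8 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. Type I interferon genes had a median of 0.83 (0.38 without AD 3), with 21 of 23 above 0 and 0 passing over all genes or adjusted over the list alone (adjusted p = 0.711 with an estimated correlation), beside 8 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. AD 3 had the highest level of the 12 libraries, at 5.36.

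Several genes of itch and inflammation fell under the low-count filter, and were tested with no such filter. IL22 had 16, 3, 9 and 7 reads in AD 1 to AD 4 and at most 2 in any HC or CPUO library. It passed in AD against HC (adjusted p = 0.048) and not in AD against CPUO (adjusted p = 0.165). Over all 12 libraries IL31 had 1 read, IL4 11, IL13 82, IFNG 22, CCL26 94, TAC1 99 and CALCA 40. These did not pass in any of the 3 comparisons, with adjusted p of 0.136 or more.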
